A study of Mus musculus with 72 samples.

How the data were processed

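Gene expression was measured in 36 tumours from 36 female BALB/c mice, 9 in each of 4 treatment groups. The tumours grew from 4T1, a mammary carcinoma cell line of BALB/c origin, placed in the thigh muscle on day -6; treatment followed on day 0 and the mice were killed on day 6. The groups were an isotype antibody control (400 µg), bintrafusp alfa (BA, 492 µg), radiation with the isotype antibody (RT), and both treatments together (BA+RT). BA is a fusion of an antibody against PD-L1 with the extracellular part of a TGF-β receptor that binds TGF-β; the label of the samples gives its code name M7824. The labels call the tissue an orthotopic tumour while the design text places the cells in the thigh, and the radiation dose is not given in the sources used here.

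Each tumour RNA was read with 2 targeted amplicon panels, so the 36 mice gave 72 libraries. Per the labels, one panel covers immuno-oncology genes, and the other was custom-built from gene sets for TGF-β targets, DNA damage, DNA repair and fibrosis. The labels do not state which of these is called panel 1 and which panel 2 in the table. Panel 1 held 992 gene amplicons and panel 2 held 286, for 1224 different genes, with 54 genes on both panels. The deposited count table held whole-number counts per amplicon, not normalized, per the file headers and the values. Whether reads or molecular barcodes were counted, the aligner and the counter are not given in the sources used here. A second deposited table held log2-scale values from the regularized log of DESeq2, a tool the submitters' processing notes name without a version. It was used for 1 alternative test. No column of another sample was present in either table.

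The position columns are headed GRCh38, and the submitters' processing notes list both GRCm38 and GRCh38. The amplicon positions were therefore compared with the GENCODE annotation of GRCm38, and 1277 of 1278 gene amplicons lay inside the mouse gene named beside them, so positions are given on GRCm38. Of these amplicons 789 lay in coding exons, 227 in 3' untranslated regions and 224 across both. Each panel also held 5 genomic DNA control rows, which had 7 counts on panel 1 and 12 on panel 2 over all libraries. These rows were left out of the totals and the tests, and their share of all counts was 2.32e-05%.

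Total counts per library ranged from 959532 to 2616197 on panel 1 and from 314621 to 841046 on panel 2. The 10 most abundant genes took 27.9% of the counts on panel 1 and 36.0% on panel 2. Replicate libraries of a group differed by more than sampling noise in every pair, with a chi-square of at least 6.32 per degree of freedom. No library thus appeared to be present more than once within a group. Libraries of different groups were not compared in this way. Of the genes on both panels 51 were tested on each, and the median correlation of their log2 CPM over mice was 0.898. A gene on both panels was reported from the panel with its larger total.

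Groups, comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined, except where stated. Counts were tested with edgeR 4.0.16 (R 4.3.3). Each panel was fitted on its own with all 4 groups, TMM normalization, the default expression filter by group, and the robust quasi-likelihood F test, two-sided. Of the 1224 genes 1038 passed the filter. Adjusted p values follow Benjamini and Hochberg over the 1038 genes, and a gene was called below 0.05. The standard error (SE) beside a log2 fold change is the absolute log2 fold change divided by the square root of the F statistic. The pairwise comparisons were 5, and the interaction tested whether the change with BA differed between irradiated and unirradiated tumours. Mouse numbers were not shared between groups, so no mice were paired. TMM sets changes relative to the bulk of the genes on each targeted panel, not to total RNA. Factors from the 9 reference genes marked on the panels moved the median log2 fold change of all genes by more than 0.1 in 3 comparisons, and the splits of calls under both scalings are given in the results.

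Gene lists were scored per mouse as the mean log2 CPM (prior count 2) of the tested members. Of 34 lists 29 had at least 4 tested members and were scored. Scores of 2 groups were compared with a two-sided exact permutation test over all 48620 arrangements of the 18 mice, which cannot give a p below 4.11e-05, and adjusted over the 29 lists. A count such as 9 of 9 mice refers to the treated group, or to BA+RT where both were treated. It gives the mice whose score lay beyond the mean of the other group, in the direction of the difference. The 2 groups can still overlap, and no change within a mouse was measured. The interaction of list scores was added after seeing the data and used 100000 permutations of the residuals of the additive model. Adjusted p values for single genes are from edgeR, and those for list scores are from the exact permutation test. The camera test of limma 3.58.1 with an estimated correlation between genes compares a list with the other genes on the panels. It called 0 of the 29 lists in each comparison, while 3 to 9 lists were called with its preset correlation of 0.01 in the comparisons other than BA+RT with RT, where 2 were called; the exact test of scores compares mice and does not set a list against other genes.

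Genes were named by a fixed rule. The rule takes the called genes with the largest rises and falls (mean of at least 10 counts), the members with the smallest p in each list with a called score or at least 3 called members, and 8 genes named in advance. The text gives a part of them. Of those 8 genes Col1a1 was not among the genes tested. Levels are CPM within a panel, as mean ± SD over 9 mice.

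The test was checked on simulated counts drawn from the means and totals of these libraries. A minority of the genes was changed, equally up and down, and genes were drawn independently of each other. The check therefore does not cover a scaling error or noise shared between genes. In the comparison of RT with control it recovered 50 of 50 genes changed 4-fold, 45 of 49 changed 2-fold, 38 of 50 changed 1.5-fold and 21 of 50 changed 1.25-fold, with 3 calls among 837 unchanged genes. For BA against control the recovery was 50 of 50, 46 of 49, 41 of 50 and 24 of 50, with 6 calls among 840, and for BA+RT against control it was 50 of 50, 46 of 50, 42 of 50 and 20 of 50, with 7 calls among 832.

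Alternatives changed the test (DESeq2 1.42.0, limma on the deposited log2 values), the normalization, the low-count filter, the adjustment, the panel used for shared genes, the groups in the fit, the way a list was scored and the libraries included. Granzymes and MHC class II genes belong to families with related sequences, and how reads matching several genes were treated is not given in the sources used here.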

Results

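Transcripts of immune, TGF-β, DNA damage, DNA repair and fibrosis genes were measured in 36 tumours grown from 4T1 mouse mammary carcinoma cells, 6 days after treatment. The 4 groups of 9 mice received an isotype control antibody, bintrafusp alfa (BA), radiation with the isotype antibody (RT) or both treatments (BA+RT). The design asks what each treatment changed, whether BA added to RT and RT to BA, and whether the change with BA depended on radiation. A library of panel 1 held a mean of 1515431 ± 268293 counts in control tumours (SD, n = 9), 1394018 ± 248885 with BA, 1949641 ± 350859 with RT and 1926244 ± 138420 with BA+RT. Panel 2 gave 546559 ± 142096, 439792 ± 133875, 649753 ± 79476 and 685066 ± 80208 in the same order. Both irradiated groups were thus sequenced more deeply than the others. The first 3 principal components of the log2 CPM values held 36%, 17.3% and 13.4% of the variance.

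In tumours that received RT, genes induced by type I interferon were higher and genes of MHC class II antigen presentation were lower than in control tumours. Oasl1, a member of the 2'-5'-oligoadenylate synthetase-like antiviral family, rose 6.78-fold from 185 ± 33.3 CPM to 1257 ± 121 CPM (SD, n = 9; log2 fold change 2.76, SE 0.11, edgeR adjusted p = 3.24e-21). H2-Aa, the alpha chain of the class II molecule I-A, was 8.02-fold lower, at 359 ± 115 CPM against 2880 ± 1600 CPM (log2 fold change -3.00, SE 0.34, adjusted p = 1.04e-08). The monocyte attractant Ccl2 rose 5.03-fold, from 613 ± 162 CPM to 3082 ± 695 CPM (log2 fold change 2.33, SE 0.26, adjusted p = 7.63e-09). Cdkn1a, the p53 target that encodes the cell cycle inhibitor p21, rose 2.63-fold from 1130 ± 616 CPM to 2949 ± 618 CPM (log2 fold change 1.40, SE 0.19, adjusted p = 3.5e-07). The amplicons lie in coding exons on GRCm38: Oasl1 on chromosome 5 at 114928141 to 114928230, H2-Aa on 17 at 34283620 to 34283724, Ccl2 on 11 at 82037010 to 82037104 and Cdkn1a on 17 at 29098452 to 29098558.

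Of 11 tested type I interferon-stimulated genes 9 rose, 0 fell and 2 were not called, with 9 called when adjusted over the list alone. Oas2 rose by 2.23 on the log2 scale and Ddx58, the RNA sensor RIG-I, by 0.93. The score of the list rose 2.47-fold, from 8.59 ± 0.40 to 9.89 ± 0.19 (exact permutation test, adjusted p = 0.000397), in 9 of 9 mice (adjusted p = 0.551 with an estimated correlation). Among the 5 tested genes of MHC class II antigen presentation 4 fell and 1 rose, with 5 called when adjusted over the list alone. H2-Ab1, the beta chain of I-A, fell by 2.81 on the log2 scale, and Cd74, the invariant chain, fell by 2.03. The class II score was 3.26-fold lower, at 7.65 ± 0.31 against 9.35 ± 0.59 (exact permutation test, adjusted p = 0.000397), in 9 of 9 mice (adjusted p = 0.747 with an estimated correlation). Ciita, the master transcriptional activator of class II genes, fell by 2.06 (SE 0.42, adjusted p = 0.000175), and by 1.29 without control mouse 8 (adjusted p = 0.000945). The 15 genes of the interferon-gamma axis, which hold Ciita, differed by 0.17 in their score (exact permutation test, adjusted p = 0.715). The mean log2 fold change over the members was -0.23. Control mouse 8 had an axis score of 9.223, against 7.736 for the next highest control mouse. The SD was 0.865 in control and 0.272 in RT tumours, so the missing call does not show an unchanged axis.

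Inflammatory myeloid genes were higher after RT. Of 10 tested members 7 rose, 0 fell and 3 were not called, with 7 called when adjusted over the list alone, among them Ccl3, 2.73-fold higher, and Tnf, 2.3-fold higher. Their score rose 1.91-fold (exact permutation test, adjusted p = 0.000397), in 9 of 9 mice (adjusted p = 0.551 with an estimated correlation). Of 7 neutrophil chemoattractants and growth factors 4 rose and 0 fell, with 4 called when adjusted over the list alone. The score rose 1.64-fold (exact permutation test, adjusted p = 0.00287), in 9 of 9 mice (adjusted p = 0.777 with an estimated correlation). The p53 target list went both ways, with 3 of 8 genes up, 3 down and 2 not called, and the same numbers when adjusted over the list alone. Cdkn1a and the death receptor Fas (log2 fold change 0.75) were among those that rose. Ddb2, a sensor of ultraviolet damage, was among those that fell, by 0.31. The mean score of the list was 1.16-fold higher (exact permutation test, adjusted p = 0.00179), in 9 of 9 mice (adjusted p = 0.812 with an estimated correlation). The median over its members per mouse differed by -0.08. Trp53, the p53 gene itself, rose by 0.43 (SE 0.05, adjusted p = 1.1e-07).

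Other genes with large changes after RT included Ccl5 (log2 fold change 2.71, SE 0.19, adjusted p = 2.19e-13), a chemokine for T cells and monocytes, and Muc1 (2.32, SE 0.22, adjusted p = 3.41e-10), an epithelial mucin. The epithelial adhesion gene Epcam fell by 0.81 (SE 0.11, adjusted p = 2.95e-07). Tnfsf4, the ligand of the costimulatory receptor OX40, rose from 2.49 ± 1.26 CPM to 12.0 ± 3.75 CPM. The granzyme gene Gzmm (log2 fold change 1.56) and the inhibitory receptor gene Tigit (1.04) also rose. Pdcd1lg2, which encodes the PD-1 ligand PD-L2, fell by 2.05, and Kynu, an enzyme of tryptophan breakdown, fell by 1.79. The scores of dendritic cell markers (difference -0.36, adjusted p = 0.00443, 9 of 9 mice) and regulatory T cell genes (-0.26, adjusted p = 0.0125, 8 of 9 mice) fell, both with an adjusted p = 0.777 with an estimated correlation. Of 6 dendritic cell markers 0 rose, 3 fell and 3 were not called, and of 10 regulatory T cell genes 1 rose, 3 fell and 6 were not called. Adjusted over the list alone, 3 and 5 were called. Among the latter, Tnfrsf18 fell by 0.75 and Ctla4 by 1.44. The score of T cell markers differed more, by -0.60, but did not pass the test (exact permutation test, adjusted p = 0.123, 8 of 9 mice; adjusted p = 0.777 with an estimated correlation). Of 16 T cell markers 0 rose, 3 fell and 13 were not called, with 2 called when adjusted over the list alone. Cd2, an adhesion molecule of T cells, was 2.38-fold lower (adjusted p = 0.00837), and 3.63-fold lower without RT mouse 24 (adjusted p = 4.1e-05). Cd8a, a marker of CD8 T cells, did not pass the test (log2 fold change -1.14, adjusted p = 0.181), and did without this mouse (-1.91, adjusted p = 0.0272). Non-homologous end joining genes fell in score by 0.18 (adjusted p = 0.00398, 9 of 9 mice; adjusted p = 0.747 with an estimated correlation), with 4 of 6 lower, 1 higher and 5 called when adjusted over the list alone, including Xrcc5 (-0.38) and Xrcc4 (-0.48). Nucleotide excision repair genes, of which 1 of 20 rose and 5 fell (6 called when adjusted over the list alone), had a score difference of -0.05 (adjusted p = 0.0102, 9 of 9 mice; adjusted p = 0.777 with an estimated correlation) that turned to 0.11 under factors from the panels' reference genes. The 21 tested TGF-β pathway and target genes differed by 0.01 in score (adjusted p = 0.883), and by 0.18 under the reference genes (adjusted p = 0.00139).

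In all, 432 of 1038 genes were called between RT and control tumours, 213 higher and 219 lower, and 505 had an unadjusted p under 0.05. The balance of rises and falls rested on the scaling. Factors from the reference genes put the median log2 fold change at 0.188, against -0.00976 as reported, and gave 422 rises and 79 falls. With these factors the scores of end joining genes (adjusted p = 0.832), regulatory T cell genes (0.638) and dendritic cell markers (0.166) were no longer called, nor was Ddb2 (adjusted p = 0.114). As medians over members, end joining genes (adjusted p = 0.142), nucleotide excision repair genes (0.946) and neutrophil chemoattractants (0.0848) were not called, nor were the first 2 with total counts (0.0533 and 0.428).

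**Figure D1:**
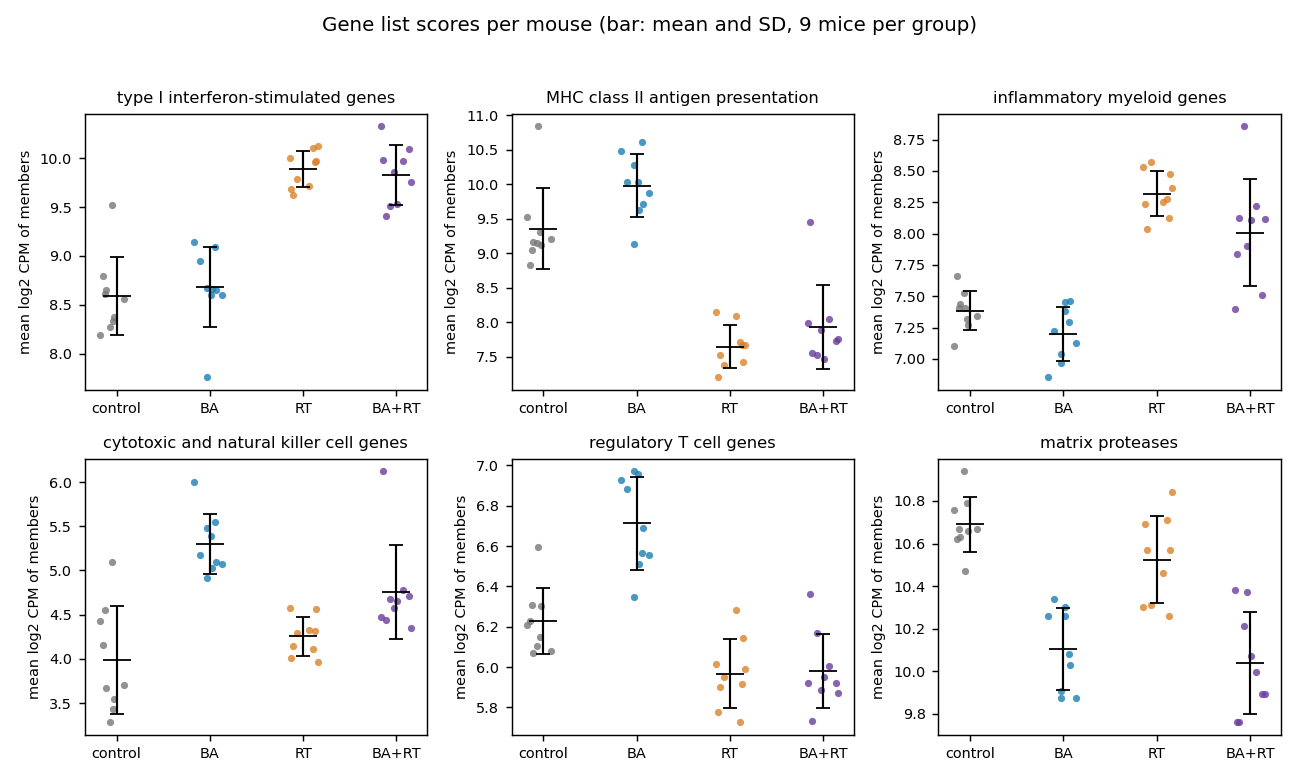
Scores of 6 lists in each mouse (mean log2 CPM of the tested members; 9 mice per group, bars are the mean and SD). The score of type I interferon-stimulated genes was 8.59 ± 0.40 in control and 9.89 ± 0.19 in RT tumours, and that of cytotoxic and natural killer cell genes 3.99 ± 0.61 in control and 5.30 ± 0.34 in BA tumours.

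Tumours that received BA had higher levels of cytotoxic lymphocyte genes and lower levels of matrix protease and fibroblast genes than control tumours. Prf1, the pore-forming protein perforin, rose 15.8-fold from 5.64 ± 4.61 CPM to 90.4 ± 44.2 CPM (SD, n = 9; log2 fold change 3.98, SE 0.51, edgeR adjusted p = 7.03e-07). Gzmb, the protease granzyme B, rose 7.58-fold from 30.4 ± 31.2 CPM to 232 ± 113 CPM (log2 fold change 2.92, SE 0.49, adjusted p = 3.59e-05). Mmp9, a gelatinase made by myeloid cells and others, was 4.79-fold lower, at 1560 ± 380 CPM against 7479 ± 1380 CPM (log2 fold change -2.26, SE 0.17, adjusted p = 1.73e-12). The largest rise was that of Ctsg, a serine protease of neutrophil and mast cell granules, which went 20.3-fold up from 2.14 ± 1.97 CPM to 48.6 ± 21.1 CPM (log2 fold change 4.34, SE 0.57, adjusted p = 8.31e-07). Their amplicons lie in coding exons on GRCm38: Prf1 on chromosome 10 at 61303348 to 61303439, Gzmb on 14 at 56260218 to 56260311, Mmp9 on 2 at 164951146 to 164951240 and Ctsg on 14 at 56099983 to 56100073.

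Of 17 tested cytotoxic and natural killer cell genes 10 rose, 1 fell and 6 were not called, with 13 called when adjusted over the list alone. Nkg7, a cytotoxic granule protein, rose by 2.22 on the log2 scale, and the granzyme gene Gzma by 2.21. Their score rose 2.49-fold, from 3.99 ± 0.61 to 5.30 ± 0.34 (exact permutation test, adjusted p = 0.000957), in 9 of 9 mice (adjusted p = 0.399 with an estimated correlation). Of 16 T cell markers 7 rose, 0 fell and 9 were not called, with 14 called when adjusted over the list alone. Cd3g, part of the T cell receptor complex, rose by 1.58 and the lymph node homing receptor gene Ccr7 by 0.94. The T cell score rose 1.89-fold (exact permutation test, adjusted p = 0.015), in 9 of 9 mice (adjusted p = 0.444 with an estimated correlation). Cd8a, with 1 to 25 counts per control library and 1 to 19 per BA library, did not pass the test (log2 fold change 0.61, SE 0.61, adjusted p = 0.513).

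Regulatory T cell genes rose as well. Of 10 tested members 5 rose, 2 fell and 3 were not called, with 7 called when adjusted over the list alone. The score rose 1.40-fold, from 6.23 ± 0.16 to 6.71 ± 0.23 (exact permutation test, adjusted p = 0.00139), in 9 of 9 mice (adjusted p = 0.399 with an estimated correlation). Foxp3, the lineage factor of regulatory T cells, rose from 6.45 ± 2.24 CPM to 19.6 ± 5.84 CPM (log2 fold change 1.60, SE 0.24, adjusted p = 8.17e-06). The IL-2 receptor gene Il2ra rose by 1.53, Tnfrsf18 by 1.12 and the inhibitory receptor gene Ctla4 by 1.80. Of 24 immune checkpoint and costimulatory genes 8 rose, 2 fell and 14 were not called, with 11 called when adjusted over the list alone. The score rose 1.35-fold (exact permutation test, adjusted p = 0.00936), in 9 of 9 mice (adjusted p = 0.444 with an estimated correlation). Tnfrsf4, the receptor OX40, rose by 0.77, and Cd40, a costimulatory receptor of antigen-presenting cells, fell by 0.88. Cd274, which encodes the PD-L1 that BA binds, did not pass the test (log2 fold change 0.19, SE 0.33, adjusted p = 0.714), and was called without control mouse 8 (log2 fold change 0.82, adjusted p = 0.0091). Dendritic cell markers, of which 3 of 6 rose and 0 fell (3 called when adjusted over the list alone), had a score 1.35-fold higher (exact permutation test, adjusted p = 0.000957), in 9 of 9 mice (adjusted p = 0.399 with an estimated correlation). Scored by the median over members, they differed by 0.19 (adjusted p = 0.257). Class II genes, of which 1 of 5 rose and 0 fell, had a score difference of 0.62 that did not pass the exact test (adjusted p = 0.0534), and did without control mouse 8 and BA+RT mouse 40 (adjusted p = 0.00268).

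Genes of the tumour matrix were lower with BA. Of 10 matrix proteases 0 rose, 6 fell and 4 were not called, with 8 called when adjusted over the list alone, of which 1 was higher. Mmp13, a collagenase, fell by 1.14 and Plau, the urokinase activator of plasminogen, by 0.69. The protease score was 1.51-fold lower, at 10.10 ± 0.19 against 10.69 ± 0.13 (exact permutation test, adjusted p = 0.000596), in 9 of 9 mice (adjusted p = 0.275 with an estimated correlation). Of 6 fibroblast markers 0 rose, 4 fell and 2 were not called, with 4 called when adjusted over the list alone. The score was 1.56-fold lower, at 9.46 ± 0.17 against 10.11 ± 0.25 (exact permutation test, adjusted p = 0.000596), in 9 of 9 mice (adjusted p = 0.399 with an estimated correlation). Cspg4, the proteoglycan NG2 of pericytes, fell by 1.72 and Fap, fibroblast activation protein, by 0.85. Among 10 extracellular matrix genes 4 fell, 2 rose and 4 were not called, with 8 called when adjusted over the list alone. The score fell by 0.32 (exact permutation test, adjusted p = 0.000796), in 9 of 9 mice (adjusted p = 0.444 with an estimated correlation). Col1a2, a chain of collagen I, fell by 0.79 and the protease inhibitor gene Timp1 by 0.92.

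The list of TGF-β pathway and target genes went both ways, with 6 of 21 members up, 5 down and 10 not called, and 11 called when adjusted over the list alone. Its score differed by -0.05 (exact permutation test, adjusted p = 0.344), its mean log2 fold change was -0.05 and its median was 0.02. The difference was -0.28 as a median over members per mouse (adjusted p = 0.00136) and -0.14 under the reference genes (adjusted p = 0.0184). Tgfb2, the ligand TGF-β2, was 2.22-fold lower (adjusted p = 4.16e-06), and Tgfb1 did not pass the test (log2 fold change -0.04, adjusted p = 0.755). The angiogenic factor gene Vegfa fell by 0.39 (SE 0.11, adjusted p = 0.00737). Rab38, a small GTPase of lysosome-related organelles, fell by 1.64 (SE 0.25, adjusted p = 6.45e-06). Of 9 proliferation genes 0 rose, 6 fell and 3 were not called, with 7 called when adjusted over the list alone, and Mki67, the Ki-67 antigen of cycling cells, fell by 0.35. Their score was 1.19-fold lower (exact permutation test, adjusted p = 0.0194), in 9 of 9 mice (adjusted p = 0.444 with an estimated correlation). Of 19 homologous recombination genes 0 rose and 7 fell, with 8 called when adjusted over the list alone, including Brca2 (-0.37). The score fell by 0.17 (exact permutation test, adjusted p = 0.0217), in 9 of 9 mice (adjusted p = 0.444 with an estimated correlation). Neutrophil markers went apart, since the granule protease gene Prtn3 rose by 1.74 and the formyl peptide receptor gene Fpr2 by 1.08 while Mmp9 fell. Of 11 tested 4 rose, 1 fell and 6 were not called, with 7 called when adjusted over the list alone. The score differed by 0.18 (exact permutation test, adjusted p = 0.0642), in 8 of 9 mice (adjusted p = 0.558 with an estimated correlation). As a median over members per mouse it differed by 0.74 (adjusted p = 0.000298). Scores of macrophage markers (0.15, adjusted p = 0.0153), mismatch repair genes (-0.11, adjusted p = 0.0149) and mesenchymal transition genes (-0.10, adjusted p = 0.015) also passed the exact test in 9 of 9 mice. Of their 11, 12 and 7 members 5, 1 and 1 rose and 1, 2 and 3 fell, with 6, 3 and 4 called when adjusted over the list alone (adjusted p = 0.444, 0.745 and 0.466 with an estimated correlation). As a median over members, mismatch repair genes differed by 0.00113.

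In all, 280 genes were called between BA and control tumours, 130 higher and 150 lower, and 392 had an unadjusted p under 0.05. Factors from the reference genes gave 99 rises and 183 falls. With total counts the scores of proliferation (difference -0.26, adjusted p = 0.0559), homologous recombination (-0.17, adjusted p = 0.0719), macrophage (0.15, adjusted p = 0.0719), mismatch repair (-0.11, adjusted p = 0.0717) and mesenchymal transition genes (-0.10, adjusted p = 0.0739) kept the reported differences to 2 decimals but were no longer called. As medians over members, neither were macrophage (adjusted p = 0.116) and mesenchymal transition genes (0.0775), and the former was also lost under the reference genes (0.101). With a covariate for muscle transcripts, chosen after seeing the data, 430 genes were called.

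**Figure D2:**
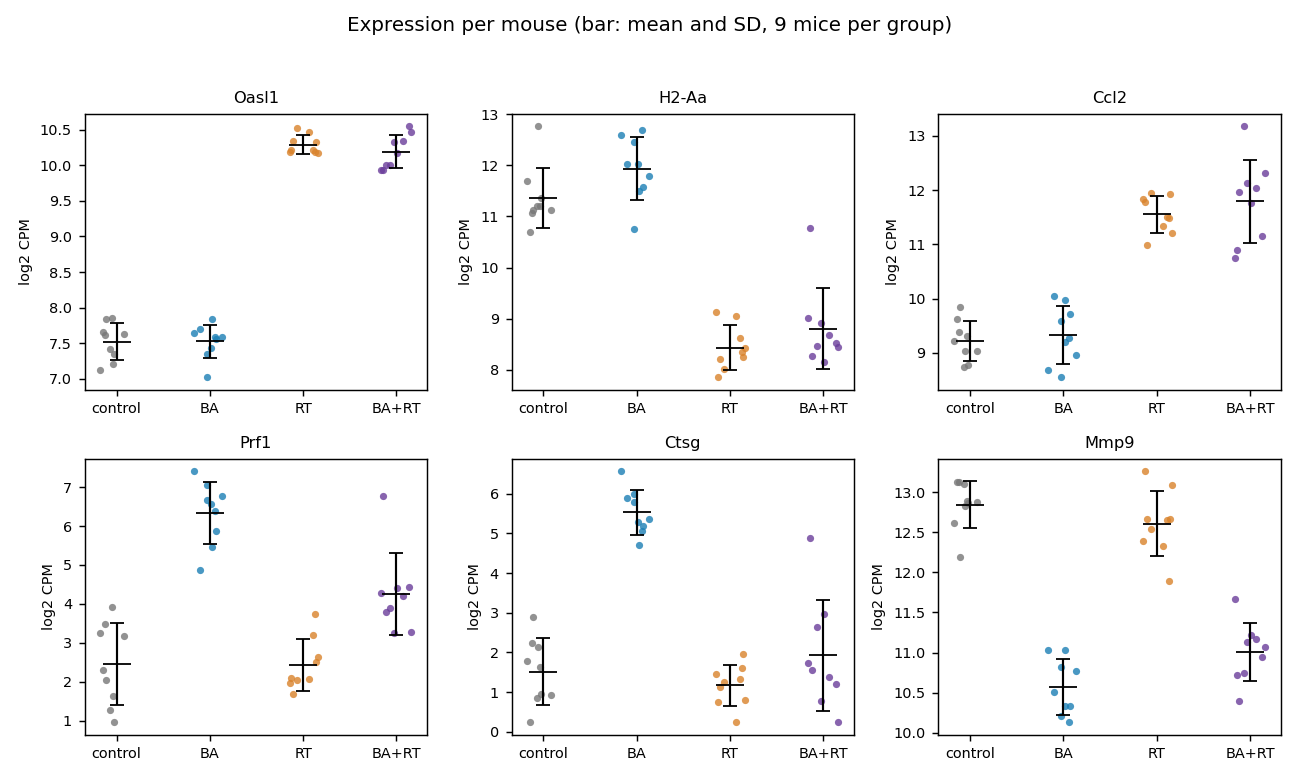
Level of 6 genes in each mouse (log2 CPM, 9 mice per group, points are mice, lines are the mean and SD). Oasl1 and Ccl2 lay higher in both irradiated groups, H2-Aa lay lower in them, Prf1 and Ctsg had their highest mean with BA (90.4 and 48.6 CPM), and Mmp9 was lower with BA and with BA+RT than in control tumours.

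Tumours that received both treatments had higher levels of interferon-stimulated and inflammatory myeloid genes and lower levels of class II and matrix protease genes than control tumours. Oasl1 was 6.38-fold higher than in control tumours, at 1183 ± 197 CPM (SD, n = 9; log2 fold change 2.67, SE 0.11, edgeR adjusted p = 8.46e-21), and Ccl2 was 6.60-fold higher at 4044 ± 2290 CPM (log2 fold change 2.72, SE 0.26, adjusted p = 3.1e-10). H2-Aa was 5.39-fold lower at 535 ± 461 CPM (log2 fold change -2.43, SE 0.33, adjusted p = 2.86e-07). Mmp9 was 3.53-fold lower at 2115 ± 543 CPM (log2 fold change -1.82, SE 0.16, adjusted p = 5.99e-11). Gzmb was 4.46-fold higher at 136 ± 168 CPM (log2 fold change 2.16, SE 0.48, adjusted p = 0.000421), with a log2 fold change of 1.41 without BA+RT mouse 40 (adjusted p = 0.00344).

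Of 11 type I interferon-stimulated genes 7 rose, 0 fell and 4 were not called, with 7 called when adjusted over the list alone. The score rose 2.36-fold to 9.83 ± 0.31 (exact permutation test, adjusted p = 0.00119), in 9 of 9 mice (adjusted p = 0.659 with an estimated correlation). Of 5 class II genes 4 fell and 1 rose, with 5 called when adjusted over the list alone. The score was 2.68-fold lower at 7.93 ± 0.61 (exact permutation test, adjusted p = 0.00159), in 8 of 9 mice (adjusted p = 0.798 with an estimated correlation). Of 10 matrix proteases 1 rose, 7 fell and 2 were not called, with 8 called when adjusted over the list alone. The score was 1.57-fold lower (exact permutation test, adjusted p = 0.00119), in 9 of 9 mice (adjusted p = 0.659 with an estimated correlation). Mmp12, the elastase of macrophages, fell by 0.97. Of 6 fibroblast markers 0 rose and 4 fell, with 4 called when adjusted over the list alone. The score was 1.60-fold lower (exact permutation test, adjusted p = 0.0012), in 9 of 9 mice (adjusted p = 0.659 with an estimated correlation). Cspg4 fell by 1.58 and Fap by 0.93.

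Of 17 cytotoxic and natural killer cell genes 6 rose, 1 fell and 10 were not called, with 7 called when adjusted over the list alone. The score rose 1.70-fold to 4.75 ± 0.53 (exact permutation test, adjusted p = 0.0224), in 9 of 9 mice (adjusted p = 0.803 with an estimated correlation). Of 16 T cell markers 0 rose, 4 fell and 12 were not called, with 0 called when adjusted over the list alone. Their score differed by -0.38 (exact permutation test, adjusted p = 0.211), in 8 of 9 mice (adjusted p = 0.803 with an estimated correlation). Cd2 fell by 1.17. Of 10 inflammatory myeloid genes 5 rose, 1 fell and 4 were not called, with 7 called when adjusted over the list alone. The score rose 1.54-fold (exact permutation test, adjusted p = 0.00307), in 9 of 9 mice (adjusted p = 0.803 with an estimated correlation). Ccl7, another monocyte attractant, rose by 2.41, and Ch25h, the interferon-induced cholesterol 25-hydroxylase, by 2.26. Cxcl13, a B cell attractant, fell by 2.51 (SE 0.68, adjusted p = 0.0029), and by 1.75 without control mouse 3 (adjusted p = 0.022). Cdkn1a rose by 1.31 (SE 0.19, adjusted p = 9.73e-07), and Tnfsf4 by 2.47. Tgfb1 fell by 0.27 (SE 0.07, adjusted p = 0.00291), but was not called with the muscle covariate (adjusted p = 0.0687), and Vegfa fell by 0.34 (SE 0.11, adjusted p = 0.00929), but was not called under the reference genes (adjusted p = 0.197).

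The exact test also called the scores of neutrophil chemoattractants (difference 0.56, adjusted p = 0.0326), p53 targets (0.16, adjusted p = 0.00143; the median over members was -0.05), end joining genes (-0.17, adjusted p = 0.00119), base excision repair genes (-0.10, adjusted p = 0.0058), alternatively activated myeloid genes (-0.37, adjusted p = 0.0123), regulatory T cell genes (-0.25, adjusted p = 0.0223) and dendritic cell markers (-0.32, adjusted p = 0.0167). These 7 lists had 5, 2, 1, 3, 0, 1 and 1 members up and 0, 2, 4, 8, 3, 4 and 4 down, with 5, 4, 5, 11, 3, 5 and 5 called when adjusted over the list alone. In the same order 8, 9, 9, 9, 9, 8 and 8 of 9 mice lay on the side of the difference (adjusted p = 0.803, 0.803, 0.659, 0.659, 0.72, 0.803 and 0.803 with an estimated correlation). In all, 494 genes were called between BA+RT and control tumours, 243 higher and 251 lower, and 569 had an unadjusted p under 0.05. Factors from the reference genes put the median log2 fold change at 0.143, against 0.00941 as reported, and gave 387 rises and 157 falls. The scores of base excision repair (adjusted p = 0.469), regulatory T cell (0.469), alternatively activated myeloid (0.209) and dendritic cell genes (0.308) were then no longer called. As medians over members, end joining (adjusted p = 0.0792), base excision repair (0.531), regulatory T cell (0.531) and alternatively activated myeloid genes (0.787) and neutrophil chemoattractants (0.103) were not called, nor was base excision repair with total counts (0.133).

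In irradiated tumours, 3 of 10 matrix proteases were lower and 4 of 17 cytotoxic and natural killer cell genes were higher with BA than without it. Mmp9 was 3.06-fold lower in BA+RT than in RT, at 2115 ± 543 CPM against 6467 ± 1830 CPM (SD, n = 9; log2 fold change -1.61, SE 0.16, edgeR adjusted p = 1.06e-08). Grem1, a secreted antagonist of bone morphogenetic proteins, was 2.56-fold lower, at 443 ± 102 CPM against 1135 ± 140 CPM (log2 fold change -1.36, SE 0.19, adjusted p = 4.7e-06; the amplicon lies in a coding exon on chromosome 2 at 113749800 to 113749896). Prf1 rose 5.19-fold, from 4.83 ± 3.30 CPM to 25.2 ± 31.3 CPM (log2 fold change 2.38, SE 0.50, adjusted p = 0.00185). Gzmb rose 3.71-fold, from 36.5 ± 18.4 CPM to 136 ± 168 CPM (log2 fold change 1.89, SE 0.47, adjusted p = 0.00775). BA+RT mouse 40 had the highest level of both genes in its group. Without it Prf1 rose 3.06-fold (adjusted p = 0.00893) and Gzmb was no longer called (log2 fold change 1.14, adjusted p = 0.0501).

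Of 10 matrix proteases 0 rose, 3 fell and 7 were not called, with 3 called when adjusted over the list alone. The 3 were Mmp9, Mmp12 (log2 fold change -1.23) and Mmp13 (-0.92). Their score was 1.40-fold lower, at 10.04 ± 0.24 against 10.52 ± 0.21 (exact permutation test, adjusted p = 0.0191), in 9 of 9 mice (adjusted p = 0.606 with an estimated correlation). Of 17 cytotoxic and natural killer cell genes 4 rose, 1 fell and 12 were not called, with 7 called when adjusted over the list alone. The score rose 1.41-fold, from 4.26 ± 0.22 to 4.75 ± 0.53 (exact permutation test, adjusted p = 0.0274), in 9 of 9 mice (adjusted p = 0.718 with an estimated correlation). The call of this score was lost without control mouse 8 and BA+RT mouse 40 (adjusted p = 0.0769) and under the reference genes (adjusted p = 0.0622). Cspg4 fell by 1.28, Cd40 by 0.90, Timp1 by 0.59, the macrophage scavenger receptor gene Msr1 by 0.40 and Ctgf, a matricellular TGF-β target, by 0.60. The scores of type I interferon-stimulated genes (-0.06, adjusted p = 0.795), class II genes (0.28, adjusted p = 0.47), T cell markers (0.22, adjusted p = 0.759) and regulatory T cell genes (0.01, adjusted p = 0.879) did not pass the exact test. Tgfb1 did not pass the test (log2 fold change -0.17, adjusted p = 0.134), but was called under the reference genes (adjusted p = 0.00238) and from its amplicon on the other panel (adjusted p = 0.0348).

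Transcripts of skeletal muscle, the tissue around cells placed in the thigh, differed widely between mice. Mb, the oxygen store myoglobin, chosen after its values were seen, was at 920 ± 1460 CPM in control tumours, 1687 ± 1100 CPM with BA, 1188 ± 669 CPM with RT and 1900 ± 1490 CPM with BA+RT. Ldb3, a protein of the muscle Z-disc, had the second largest called rise in this comparison, after Prf1, from 141 ± 121 CPM to 683 ± 702 CPM (log2 fold change 2.27, SE 0.75, adjusted p = 0.0445). After each group's mean was removed, Ldb3 and Mb correlated over the 36 mice with Pearson r = 0.896 and Spearman rho = 0.838 (permutation p = 1e-05 for each, the smallest that 100000 resamples can give). The first was 0.842 without control mouse 6 and BA mouse 14. Ldb3 was not called with total counts (adjusted p = 0.0502), under the reference genes (adjusted p = 0.0581) or in 11 of 18 fits that left out 1 mouse (RT mouse 21, 22, 23, 24, 25, 26 or 27, or BA+RT mouse 38, 41, 42 or 45), the last of which gave 1.75 (adjusted p = 0.113). Ctsg (log2 fold change 2.04, adjusted p = 0.0358) was not called in 7 of 18 (RT mouse 19, 20, 22, 23 or 24, or BA+RT mouse 40 or 43), with 0.90 (adjusted p = 0.344) without mouse 40, nor by limma on the deposited log2 values (adjusted p = 0.301). In all, 112 genes were called between BA+RT and RT, 38 higher and 74 lower, and 257 had an unadjusted p under 0.05. The reference genes gave 19 rises and 96 falls, and the muscle covariate 278 calls, 130 higher and 148 lower. Without control mouse 6 and BA+RT mouse 45, the mice with the highest muscle levels, 177 genes were called, 70 higher and 107 lower.

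In tumours that received BA, the addition of RT raised interferon-stimulated and inflammatory myeloid genes and lowered class II, T cell and regulatory T cell genes. Oasl1 was 6.39-fold higher in BA+RT than in BA, at 1183 ± 197 CPM against 185 ± 28.5 CPM (SD, n = 9; log2 fold change 2.68, SE 0.11, edgeR adjusted p = 8.48e-21). H2-Ab1 was 8.93-fold lower, at 238 ± 183 CPM against 2124 ± 746 CPM (log2 fold change -3.16, SE 0.31, adjusted p = 7.02e-10; the amplicon lies in the 3' UTR on chromosome 17 at 34269137 to 34269231). Ctla4 was 8.60-fold lower, at 3.32 ± 3.73 CPM against 29.5 ± 13.1 CPM (log2 fold change -3.11, SE 0.44, adjusted p = 6.94e-07). Foxp3 was 4.06-fold lower, at 4.76 ± 1.88 CPM against 19.6 ± 5.84 CPM (log2 fold change -2.02, SE 0.24, adjusted p = 2.7e-08; the amplicon lies in the 3' UTR on chromosome X at 7593514 to 7593608). Ctsg was 9.02-fold lower, at 5.22 ± 8.93 CPM against 48.6 ± 21.1 CPM (log2 fold change -3.17, SE 0.51, adjusted p = 3.69e-06), and 19.8-fold lower without BA+RT mouse 40 (adjusted p = 8.87e-10).

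Of 5 class II genes 4 fell and 1 rose, with 5 called when adjusted over the list alone. The score was 4.12-fold lower (exact permutation test, adjusted p = 0.000341), in 9 of 9 mice (adjusted p = 0.452 with an estimated correlation). Of 16 T cell markers 0 rose, 13 fell and 3 were not called, with 13 called when adjusted over the list alone. The score was 2.46-fold lower, at 2.96 ± 0.41 against 4.26 ± 0.57 (exact permutation test, adjusted p = 0.000435), in 9 of 9 mice (adjusted p = 0.452 with an estimated correlation). Cd2 was 4.94-fold lower and Ccr7 2.82-fold lower. Of 10 regulatory T cell genes 1 rose, 5 fell and 4 were not called, with 6 called when adjusted over the list alone. The score was 1.66-fold lower (exact permutation test, adjusted p = 0.000341), in 9 of 9 mice (adjusted p = 0.452 with an estimated correlation). Of 24 checkpoint and costimulatory genes 5 rose, 12 fell and 7 were not called, with 18 called when adjusted over the list alone. The score was 1.41-fold lower (exact permutation test, adjusted p = 0.00204), in 8 of 9 mice (adjusted p = 0.452 with an estimated correlation). Pdcd1lg2 fell by 2.86 and Tnfrsf18 by 1.90, while Tigit rose by 1.40. Of 6 dendritic cell markers 1 rose, 4 fell and 1 was not called, with 5 called when adjusted over the list alone. The score was 1.69-fold lower (exact permutation test, adjusted p = 0.000341), in 9 of 9 mice (adjusted p = 0.452 with an estimated correlation). Of 17 cytotoxic genes 3 rose, 8 fell and 6 were not called, with 11 called when adjusted over the list alone. The score fell by 0.55 (exact permutation test, adjusted p = 0.0333), in 8 of 9 mice (adjusted p = 0.866 with an estimated correlation). Gzmm rose by 1.29, and Gzmb did not pass the test (log2 fold change -0.77, adjusted p = 0.151) except by limma (adjusted p = 0.0171) and without BA+RT mouse 40 (log2 fold change -1.52, adjusted p = 0.0012).

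Of 11 type I interferon-stimulated genes 7 rose and 0 fell, with 7 called when adjusted over the list alone. The score rose 2.21-fold (exact permutation test, adjusted p = 0.000341), in 9 of 9 mice (adjusted p = 0.452 with an estimated correlation). Of 10 inflammatory myeloid genes 8 rose, 1 fell and 1 was not called, with 9 called when adjusted over the list alone. The score rose 1.75-fold (exact permutation test, adjusted p = 0.000435), in 9 of 9 mice (adjusted p = 0.452 with an estimated correlation). Ccl2 rose by 2.56 and Ccl3 by 1.59. Of 7 neutrophil chemoattractants 6 rose and 0 fell, with 6 called when adjusted over the list alone. The score rose 1.87-fold (exact permutation test, adjusted p = 0.00156), in 9 of 9 mice (adjusted p = 0.452 with an estimated correlation). Of 9 proliferation genes 7 rose, 1 fell and 1 was not called, with 9 called when adjusted over the list alone. The score rose 1.27-fold (exact permutation test, adjusted p = 0.000396), in 9 of 9 mice (adjusted p = 0.499 with an estimated correlation). Of 19 homologous recombination genes 11 rose, 1 fell and 7 were not called, with 12 called when adjusted over the list alone. The score rose by 0.26 (exact permutation test, adjusted p = 0.000341), in 9 of 9 mice (adjusted p = 0.462 with an estimated correlation). Mismatch repair genes had 4 of 12 members up and 6 down, and 10 called when adjusted over the list alone, with a score difference of 0.15 (exact permutation test, adjusted p = 0.000341), in 9 of 9 mice, but a median log2 fold change of -0.18 and a downward direction in camera (adjusted p = 0.866 with an estimated correlation). Msh4, a meiotic member of that list, rose by 2.47 from 5.07 ± 4.04 CPM.

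Muc1 rose by 2.86 (SE 0.23, adjusted p = 7.06e-12), and Kit, the stem cell factor receptor of mast cells, fell by 1.95 (SE 0.18, adjusted p = 1.28e-10). The largest fall was that of Igkc, the immunoglobulin kappa constant region, by 3.69 (SE 1.09, adjusted p = 0.00511), which was not called by limma on the deposited log2 values (adjusted p = 0.0628). Igkc fell by 2.80 without BA mouse 11 (adjusted p = 0.0261) and by 4.47 without BA+RT mouse 40 (adjusted p = 0.0021). Scores of end joining (-0.18, adjusted p = 0.000396), base excision repair (-0.10, adjusted p = 0.000341), p53 target (0.13, adjusted p = 0.000894), checkpoint kinase (0.07, adjusted p = 0.015) and neutrophil marker genes (-0.30, adjusted p = 0.00462) passed the exact test. Base excision repair turned to 0.06 under the reference genes while the p53 target and checkpoint kinase lists turned to -0.13 and -0.11 as medians over members. These 5 lists had 0, 1, 2, 7 and 3 members up and 4, 7, 2, 5 and 5 down, with 5, 8, 4, 12 and 8 called when adjusted over the list alone. In the same order 9, 9, 9, 8 and 9 of 9 mice lay on the side of the difference (adjusted p = 0.452, 0.452, 0.866, 0.866 and 0.583 with an estimated correlation). In all, 555 genes were called between BA+RT and BA, 281 higher and 274 lower, and 611 had an unadjusted p under 0.05. Factors from the reference genes put the median log2 fold change at 0.199, against 0.0206 as reported, and gave 472 rises and 147 falls. The scores of cytotoxic (adjusted p = 0.175), end joining (0.463) and neutrophil marker genes (0.223) were then not called. As medians over members, cytotoxic (0.0814), base excision repair (0.39) and mismatch repair genes (0.913) were not called, nor was base excision repair with total counts (0.0786).

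The interaction, the difference between the change with BA in irradiated and in unirradiated tumours, was called for 86 genes, 35 with a positive and 51 with a negative value, and 237 had an unadjusted p under 0.05. Msr1, a scavenger receptor of macrophages, had the smallest p value, with an interaction of -0.84 on the log2 scale (SE 0.13, edgeR adjusted p = 0.000138). It stood at 301 ± 49.3 CPM in control tumours, 409 ± 62.4 CPM with BA, 421 ± 51.3 CPM with RT and 320 ± 29.6 CPM with BA+RT (SD, n = 9). Itm2a, a membrane protein gene on chromosome X at 107398099 to 107398193, had the largest positive value (1.13, SE 0.20, adjusted p = 0.000789), at 1870 ± 464, 904 ± 156, 1295 ± 287 and 1366 ± 283 CPM in the same order. Foxp3 had an interaction of -1.38 (SE 0.36, adjusted p = 0.0125), at 6.45 ± 2.24, 19.6 ± 5.84, 4.09 ± 1.89 and 4.76 ± 1.88 CPM.

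Regulatory T cell genes had a score interaction of -0.47 (permutation test, adjusted p = 0.0261; adjusted p = 0.508 with an estimated correlation), with 0 of 10 members positive, 3 negative and 7 not called, and 5 called when adjusted over the list alone. The 3 were Foxp3, Tnfrsf18 (-1.15) and Tnfrsf4 (-0.77). Macrophage markers had -0.26 (permutation test, adjusted p = 0.0277; adjusted p = 0.508 with an estimated correlation), with 5 of 11 negative, 0 positive and 5 called when adjusted over the list alone. Neutrophil markers had -0.36 (permutation test, adjusted p = 0.0277; adjusted p = 0.508 with an estimated correlation), with 3 of 11 negative, among them Fpr2 (-0.98) and the integrin gene Itgam (-0.65), and 5 called when adjusted over the list alone. Dendritic cell markers had -0.39 (permutation test, adjusted p = 0.0277; adjusted p = 0.511 with an estimated correlation), with Ccr7 (-1.21) the 1 of 6 called, also when adjusted over the list alone. Ccr7 is on the list of T cell markers as well. Cytotoxic genes had -0.82 (permutation test, adjusted p = 0.0498; adjusted p = 0.511 with an estimated correlation), with 1 of 17 members positive and 0 negative in the fit of all genes and 1 positive and 2 negative when adjusted over the list alone. Gzmb did not pass the test (-1.03, adjusted p = 0.361), and did without BA+RT mouse 40 (-1.78, adjusted p = 0.0273). Mismatch repair genes had 0.12 (permutation test, adjusted p = 0.0277; adjusted p = 0.511 with an estimated correlation), with 1 of 12 called in the fit of all genes and 1 when adjusted over the list alone. The cytokine receptor genes Il12rb2 (-1.34) and Tnfrsf25 (-1.23) had negative values. Msln, which encodes mesothelin (0.86), the transcription factor gene Egr2 (0.66) and the chromatin remodelling gene Hells (0.61) had positive ones. Matrix proteases (0.10, adjusted p = 0.666), T cell markers (-0.70, adjusted p = 0.206) and type I interferon-stimulated genes (-0.16, adjusted p = 0.666) did not pass the test.

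Over the 1038 genes, which are not independent replicates, the change with BA correlated between unirradiated and irradiated tumours with Pearson r = 0.585 and Spearman rho = 0.373. Pearson r lay between 0.414 and 0.671 when 1 mouse was left out, and its jackknife SE from these fits was 0.236. Of the genes called in both settings 48 changed in the same direction and 6 in the opposite one, with 12 both higher (4.76 for independent lists) and 36 both lower (10.7). The change with RT correlated between tumours without and with BA with r = 0.800 and rho = 0.712. In all, 299 genes called in both changed in the same direction and 11 in the opposite one, with 147 both higher (57.7 for independent lists) and 152 both lower (57.8). The 2 settings of each comparison share no libraries, although all 4 groups share the scaling and the estimate of spread. The interaction had 50 positive and 49 negative calls with the size factors of DESeq2 in edgeR and 57 and 50 with the test of DESeq2. It had 22 positive and 39 negative calls under the reference genes, and 30 and 47 with total counts. With the muscle covariate 142 genes were called. Without control mouse 8 and BA+RT mouse 40, the mice with the highest class II levels of their groups, 151 were called.

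**Figure D3:**
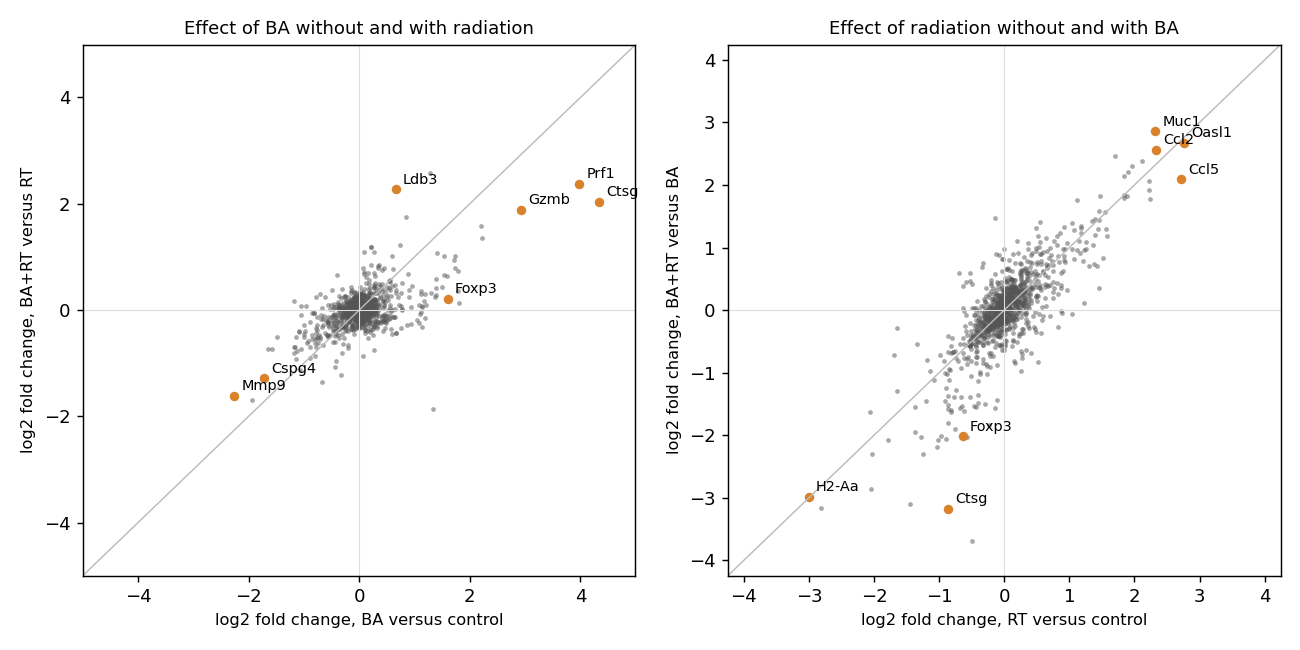
Log2 fold changes of the 1038 genes, with BA without radiation against BA with radiation and with RT without BA against RT with BA; each point is a gene and the line marks equal values. The Pearson correlations were 0.585 and 0.800.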

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

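Chosen after the results were seen were the tests of the Ctsg to Gzmb ratio, of neutrophil markers (both), of muscle transcripts (correlation and covariate), of thinning for Ldb3, Ank1 and Pcx, and of counts near zero for regulatory T cell genes, as well as the permutation test of interactions of list scores; the splits of the mice, the other thinning tests, the within-group test of library size and the muscle covariate for regulatory T cell genes were written before their results were seen, the last with Mb and Myod1 already chosen from their values.

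The changes with BA and with RT were set against 100 splits of the same mice, the real one included. For the number of genes called, 1 of 100 splits reached the real value in each of the 5 comparisons: 432 genes for RT versus control (highest other 223), 280 for BA versus control (100), 494 for BA+RT versus control (243), 112 for BA+RT versus RT (54) and 555 for BA+RT versus BA (487). For the interaction, 1 of 100 splits of BA within the irradiated and the unirradiated mice reached 86 genes (highest other 45). The correlation of 0.585 between the 2 changes with BA was reached in 3 of 100 splits (highest other 0.667), and that of 0.800 between the 2 changes with RT in 1 of 100 (highest other 0.705). Each of these 8 results was thus reached by a share of splits under 0.05, judged singly and without adjustment for 8 results. For the correlation of 0.585, a share of 3 of 100 does not exclude chance.

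The first pattern weighed was the higher level of Ldb3, Ank1 and Pcx in BA+RT than in RT, genes picked after their values were seen. Thigh muscle in the sample went with it, as the 3 genes followed Mb within the groups with a median correlation of 0.857. With Mb and Myod1 as a covariate 2 of the 3 genes stayed called. Ldb3 went from 2.27 ± 0.75 (SE) to 1.08 ± 0.28, and Pcx, from 1.19 to 0.50, was no longer called (edgeR adjusted p = 0.104). These 2 transcripts measure muscle content with error, so what is left after the covariate cannot show whether muscle was the whole difference. Thinned to equal totals, the genes kept a median log2 fold change of 1.70, against 1.75 before, while the test written beforehand, their within-group correlation with library size, gave 0.434 and decided nothing. A change of muscle tissue by the combined treatment, as against a different share of muscle in the sample, stays open and was not tested.

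The second pattern was the smaller response of regulatory T cell genes to BA in irradiated tumours, with an interaction of -0.47 in the list score; it was picked after all 29 list interactions were seen, in place of T cell markers (-0.70, adjusted p = 0.206). After thinning to equal totals the difference was -0.413 (permutation p = 0.00208), which argues against library size as the whole of it. Over the 7 of 10 members with at least 50 counts it was smaller, at -0.313 (permutation p = 0.00067). This argues against counts near zero as the whole of the difference, but members with fewer counts may hold a part of it. With the muscle covariate the difference was -0.473 (permutation p = 0.00101). No biological explanation was tested. The list was not called by camera with an estimated correlation (adjusted p = 0.508).

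The third pattern was the rise of Ctsg with BA. Reads shared with Gzmb at a fixed rate, as the whole rise, were argued against by the log2 ratio of Ctsg to Gzmb, which differed by 2.50 between BA (-2.17 ± 0.78, SD) and BA+RT (-4.67 ± 0.73; exact permutation p = 4.11e-05), and which was -3.06 ± 0.998 in control tumours, nearer to that of BA. Library size was argued against by thinning, after which the log2 fold change was 4.28 (SE 0.54, adjusted p = 4.77e-07). Ctsg rose more than each of the 11 neutrophil markers, whose upper 95% bounds reached at most 2.18 (Prtn3) against a lower bound of 3.22 for Ctsg. This cannot decide on more neutrophils as the whole rise. Markers that other cells also make would rise less, and Ctsg started near zero in control tumours. More neutrophils as part of the rise cannot be told apart from a change per cell, since the marker score differed by 0.18 (upper bound 0.331) as a mean but by 0.741 (upper bound 0.97) as a median over members.

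The change with BA differed between irradiated and unirradiated tumours, by a test of the interaction, for 86 genes and 6 lists. None of these lists was called by camera with an estimated correlation (adjusted p = 0.508 to 0.511). The interactions of list scores were not rerun with other scalings, as medians over members or without single mice. The list scores differed by -0.82 (cytotoxic and natural killer cell genes), -0.47 (regulatory T cell genes), -0.39 (dendritic cell markers), -0.36 (neutrophil markers), -0.26 (macrophage markers) and 0.12 (mismatch repair). Of the named genes, the difference was 1.13 for Itm2a, 0.86 for Msln, 0.66 for Egr2, 0.61 for Hells, 0.36 for Mki67, -0.65 for Itgam, -0.77 for Tnfrsf4, -0.84 for Msr1, -0.98 for Fpr2, -1.15 for Tnfrsf18, -1.21 for Ccr7, -1.23 for Tnfrsf25, -1.34 for Il12rb2 and -1.38 for Foxp3. Mki67 was not called in 22 of the 36 fits that left out 1 mouse, nor with total counts (adjusted p = 0.109) or the reference genes (0.146).

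Single mice far from the other 8 of their group were looked for among the library totals, the 29 list scores and the genes named in the text. By chance about 1 in 20 groups would be picked out, or 5.8 of 116 groups for lists and 14.6 of 292 for genes, against 15 and 32 found and 0 of 8 for library totals. BA+RT mouse 40 stood apart 16 times and control mouse 8 in 11.

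In control mouse 8 the scores were 10.84 for MHC class II, 9.786 for MHC class I, 9.521 for type I interferon-stimulated, 9.223 for interferon-gamma axis and 6.593 for regulatory T cell genes, and the log2 CPM was 12.77 for H2-Aa, 11.71 for H2-Ab1, 9.834 for Cd274, 9.43 for Ciita, 8.452 for Ccl5 and 7.384 for Pdcd1lg2. In BA+RT mouse 40 the scores were 9.452 for MHC class II, 8.483 for interferon-gamma axis, 6.122 for cytotoxic, 5.819 for checkpoint and 3.993 for T cell genes, and the log2 CPM was 12.51 for Cd74, 10.77 for H2-Aa, 9.49 for H2-Ab1, 9.181 for Gzmb, 8.865 for Cd274, 8.304 for Gzma, 7.661 for Ciita, 7.472 for Nkg7, 6.768 for Prf1, 5.625 for Pdcd1lg2 and 5.301 for Cd3g.

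RT mouse 24 had a T cell score of 4.366 and log2 CPM of 8.228 for Igkc, 5.251 for Cd3g and 4.536 for Cd2. BA+RT mouse 45 had a neutrophil chemoattractant score of 8.33 and log2 CPM of 12.03 for Epcam and 3.772 for Tnfrsf25. Control mouse 6 had 11.43 for Cdkn1a and 10.09 for Ldb3, and RT mouse 21 had 5.056 for Tnfrsf4 and 0.8852 for Foxp3. The others, with 1 value each, were the fibroblast score of BA mouse 16 (9.066), the type I interferon score of BA mouse 17 (7.758), the macrophage score of RT mouse 22 (8.806), and the log2 CPM of Il12rb2 in BA mouse 12 (3.22) and RT mouse 19 (2.666), Ccl5 in BA+RT mouse 37 (9.198), Mki67 in BA+RT mouse 41 (11.06), Msr1 in RT mouse 23 (9.079) and Gzma in RT mouse 26 (5.733).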

How the results depend on the processing

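The fits with the muscle covariate or without mice, and the reference genes as a scaling, were chosen after the data were seen. A summary result stayed if the alternative lay within 1.5 times the reported count or, for a correlation, within its jackknife SE. Of 120 comparisons of a summary result with an alternative 99 stayed and 21 moved. Of 870 for list scores 770 kept their direction and call, 14 reversed, 50 gained and 36 lost the call. These list scores cover the 5 pairwise comparisons and not the interaction. Of 4489 for named genes 4367 kept both, 2 reversed, 20 gained and 100 lost the call. Leaving out 1 mouse gave 399 to 483 genes for RT versus control, 242 to 349 for BA versus control, 458 to 532 for BA+RT versus control, 76 to 153 for BA+RT versus RT, 514 to 570 for BA+RT versus BA and 71 to 106 for the interaction. The muscle covariate gave 430 genes for BA versus control, 278 for BA+RT versus RT and 142 for the interaction. Without control mouse 6 and BA+RT mouse 45, 177 genes and 5 lists were called for BA+RT versus RT, and without control mouse 8 and BA+RT mouse 40, 151 genes for the interaction and 1 list for BA+RT versus RT. For lists, camera with an estimated correlation called 0 in each of the 5 comparisons, whereas 2 to 17 passed the exact test. With a preset correlation camera called 3 (RT versus control), 3 (BA+RT versus control) and 9 (BA+RT versus BA). The fry test called 14 for RT versus control and 1 for BA+RT versus RT, the median over members 4 for BA+RT versus RT, total counts 8 for BA versus control, and the reference genes 15 for RT versus control and 4 for BA+RT versus RT. Under the reference genes Itgav turned to 0.031 for RT versus control and 0.025 for BA+RT versus control, the score of mesenchymal transition genes to 0.18 (RT versus control), that of nucleotide excision repair to 0.11 (RT versus control), -0.093 (BA versus control) and 0.12 (BA+RT versus BA), and for BA+RT versus BA TGF-β genes to 0.15 and base excision repair to 0.055. As a median over members p53 targets turned to -0.076, -0.053 and -0.13 and checkpoint kinases to -0.13, -0.12 and -0.11 (RT versus control, BA+RT versus control and BA+RT versus BA), mismatch repair to 0.00113 (BA versus control) and matrix proteases to 0.50 (BA+RT versus BA). For those that moved or reversed the cause was not tested. No paired analysis was possible because replicate numbers are not shared between the groups. A factor from housekeeping genes was not run, as B2m was the only gene of that list measured, and 9 reference genes of the panels took its place. No library had under 0.2 of the median total, so the fit without such libraries gave no values.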

Other observations

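The fit without control mouse 8 and BA+RT mouse 40 and the reference genes as a scaling were chosen after the data were seen. Of 12 genes of MHC class I antigen presentation, which show peptides to CD8 T cells, 5 rose, 0 fell and 7 were not called between RT and control tumours, with 5 called when adjusted over the list alone. The score did not pass the test, with a difference of 0.30 (exact permutation test, adjusted p = 0.0739), in 9 of 9 mice (adjusted p = 0.777 with an estimated correlation). It was 0.40 without control mouse 8 and BA+RT mouse 40 (adjusted p = 0.000298) and 0.50 under the reference genes (adjusted p = 0.00966), but 0.03 as a median over members (adjusted p = 0.946). Between BA+RT and control tumours 5 of 12 rose and 0 fell, with 5 called when adjusted over the list alone. The score did not pass the test here either, with a difference of 0.27 (exact permutation test, adjusted p = 0.0907), in 8 of 9 mice (adjusted p = 0.803 with an estimated correlation). It was 0.33 without these 2 mice (adjusted p = 0.00225) and 0.43 under the reference genes (adjusted p = 0.0228), but 0.04 as a median over members (adjusted p = 0.83). Between BA and control tumours it was 0.21 (exact permutation test, adjusted p = 0.229; adjusted p = 0.745 with an estimated correlation), with 1 of 12 members up and 0 down and 1 called when adjusted over the list alone, and 0.32 without these 2 mice (adjusted p = 0.00549). Between BA+RT and BA tumours 4 of 12 rose and 2 fell, with 6 called when adjusted over the list alone. The score differed by 0.06 (exact permutation test, adjusted p = 0.694), in 7 of 9 mice (adjusted p = 0.866 with an estimated correlation), and by 0.24 under the reference genes (adjusted p = 0.0498) and -0.14 as a median over members (adjusted p = 0.222).

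Macrophage markers went both ways after RT, with 6 of 11 up, 2 down and 3 not called, and 9 called when adjusted over the list alone. Their score differed by 0.16 (exact permutation test, adjusted p = 0.111), in 8 of 9 mice (adjusted p = 0.777 with an estimated correlation), by 0.37 under the reference genes (adjusted p = 0.0143) and by 0.01 as a median over members (adjusted p = 0.961). Of 5 endothelial markers 0 rose and 3 fell between BA+RT and RT, with 3 called when adjusted over the list alone. The score differed by -0.09 (exact permutation test, adjusted p = 0.759), in 7 of 9 mice (adjusted p = 0.718 with an estimated correlation), and by -0.46 as a median over members (adjusted p = 0.0211). Mast cell and eosinophil markers, to which Kit belongs, had 1 of 7 members up and 2 down between BA+RT and BA, with 3 called when adjusted over the list alone. The score differed by -0.08 (exact permutation test, adjusted p = 0.735), in 5 of 9 mice (adjusted p = 0.866 with an estimated correlation), while the median log2 fold change was 0.12.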
